A study of Gallus gallus with 4 samples.

How the data were processed

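Total RNA was measured from the primitive streak region of chicken embryos, which holds the progenitors of the presomitic mesoderm (PSM), the unsegmented tissue that gives rise to the somites. Per the labels, eggs were incubated for 24 h at 38 °C to stage 5 of the Hamburger and Hamilton series, and the embryos were electroporated in culture and grown for a further 14 h to 9 somites. Each array held a pool of 7 embryos. In one group the vector coded for HoxA13 together with a nuclear fluorescent reporter, and in the other for the reporter alone. There were 2 arrays per group, and the labels call them biological replicates. The p-values therefore refer to the spread between pools of embryos. With so few arrays, limma takes much of each gene's spread from the other probe sets, so it is only partly measured on the gene itself. Replicates are named here by group and number as the labels give them.

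The deposited values are linear intensities, 1 per probe set of a chicken Affymetrix array. Per the labels' protocols the RNA went through a double amplification before hybridisation. R 2.12.1 is the only tool that the submitters' processing notes name. The summary method, the background correction and the scaling between arrays are not given in the sources used here, so the intensities were taken as they stood and put on a log2 scale. All values were above 0, the medians over chicken probe sets lay between 9.48 and 10.0, and the distributions of the arrays were not identical. Every column of the value table belonged to a sample of the series.

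Of 38535 probe sets, 37695 were chicken, 687 viral, 57 for reporters and 96 controls. Only the chicken probe sets were tested. Gene names came from the platform annotation supplied with the values, which gave 1 symbol for 27168 chicken probe sets, several for 177 and none for 10350. The Entrez numbers of 26853 of them were also found in a table of RefSeq genes, and 0 symbols changed by it. The 13009 distinct symbols are those of the annotation and can be old. For gene lists and genes chosen by name, the probe set with the highest mean over all 4 arrays stood for the gene.

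The planned comparison was HoxA13 minus control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on log2 intensity over all chicken probe sets, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 25 lists fixed before the data were examined. The lists held 533 genes, of which 440 were measured. Genes were named by a rule also fixed then. It took HOXA13, and per direction 12 genes that passed, filled up by the smallest unadjusted p among genes with a log2 difference of at least 1 and groups that did not overlap. It further took the 4 genes with the smallest unadjusted p in each list described, and 16 fixed genes of the progenitors and their signals, of which SP5 had no named probe set. With 2 arrays against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.333, and chance alone separates the groups without overlap in 33.3% of genes.

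Background was taken as the 99th percentile of the viral probe sets on each array, which was 14.3 and 14.5 on HoxA13 replicates 1 and 2 and 12.8 and 16.5 on control replicates 1 and 2. Where a gene was below this in every array of a group, the fold is a lower limit. It sets the bright group's mean log2 intensity against the dim group's, with each dim array raised to its own background, and is written "at least". Folds for other genes come from the planned log2 differences.

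A second fit, called the offset fit, was chosen after seeing the data. It used log2(intensity + 16), the 15818 chicken probe sets above background on at least 2 of the 4 arrays, and an eBayes prior with an intensity trend and robust estimation. Its log2 differences understate changes of dim probe sets. It was picked from 24 combinations of offset, background filter, replicate block and prior. These gave between 0 and 102 probe sets higher and between 0 and 162 lower, and 7 of them gave none. The 12 combinations without the block gave at most 3 higher and 10 lower, and these are the counts of the offset fit itself. The same combination with an offset of 32 gave 2 higher and 9 lower. The other combinations without the block gave 0 higher and at most 3 lower. A gene is said to have risen or fallen only where it passed the offset fit, or that fit with the replicate number as a block, and the sentence or paragraph says which.

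The arrays also split by replicate number. All 27 hybridisation spike-in probe sets were brighter on both replicate 2 arrays than on both replicate 1 arrays, by a median of 0.75 on the log2 scale. The spike-ins are bacterial and phage transcripts added together before hybridisation, so they count as a single observation. The labels tie the number to no day or batch. Arrays of equal number are called a batch here on the strength of the spike-ins alone, and every call made with the block rests on that. Same-numbered arrays deviated from their group means with a correlation of 0.20 over probe sets above background and 0.06 over all chicken probe sets. Each batch held 1 array of each group, so differences are given within each batch on the log2(intensity + 16) scale. The offset fit was also repeated with the batch as a block. The block leaves so little spread per gene that its p-values rest mostly on the spread shared over probe sets. For the gene FLT1 the batches differed by -2.20 and -3.32, while its standard error in that fit was 0.305. The mean log2 ratio of 3' to 5' signals of the actin, elongation factor and GAPDH controls was 4.40 and 4.93 on the HoxA13 arrays and 3.96 and 5.30 on the control arrays. In each of these controls it was higher on both replicate 2 arrays than on both replicate 1 arrays. The split by number is therefore also a split in this ratio.

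The fits were tested on simulated data with the means and the intensity-dependent spread of these arrays, in 5 runs of 200 changed probe sets each, with log2 changes of 1, 2, 3, 5 or 8. The changed probe sets were drawn from those above background on at least 2 arrays, so the shares do not hold for dim transcripts. The planned fit recovered 0 of the 1000 changed probe sets at any of these sizes, with the sign right in at least 95% of them, so a count of 0 from it does not bear on whether transcripts changed. The offset fit recovered 12% of changes of log2 1, 58% of log2 2 and 76.5% of log2 3. Of its calls 8.37% were false, above the nominal level, with 635 true and 58 false calls over the 5 runs. With the block the false share was 13.7%. Both shares depend on the number and sizes of the simulated changes. No batch difference was simulated, so the shares may not hold for these arrays. Simulated lists of 20 genes shifted by log2 1 were called in 25 of 25 cases, and 0 of 75 unshifted lists were called. Every gene of a shifted list moved by that full amount, so the 25 calls do not bear on smaller or mixed shifts. The simulated genes were independent of each other, which favours camera at its preset correlation.

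The alternatives set before the data were examined were quantile normalization, centring each array on its median, filters at the median and at the 25th percentile of the mean, the trend and robust prior, a floor at log2 of 4, the replicate block, leaving out each array, and for lists the mean of all probe sets of a gene, an estimated correlation and fry. The number of arrays limits the precision of every value.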

Results

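Gene expression was profiled in the PSM progenitor region of chicken embryos of 9 somites. The embryos had been electroporated with a vector for HoxA13 and a fluorescent reporter, or with the reporter alone. HoxA13 belongs to the posterior Hox genes, transcription factors that are switched on late during axis formation. The series holds 4 arrays, 2 for HoxA13 and 2 for the control, each from a pool of 7 embryos. Between 37.8% and 42.7% of the chicken probe sets were above background on an array. The one comparison of the design asks which transcripts differ when HoxA13 is overexpressed in the progenitors before it is normally active there. Signals, Wnt and other, that keep the progenitors in the streak are the focus of the lists below.

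The transcript of HOXA13 itself was represented by 1 probe set, which stayed near background. Its signals were 16.3 and 8.09 on the HoxA13-labelled arrays and 11.6 and 24.7 on the controls, a log2 difference of -0.55 ± 0.67 (SE, adjusted p = 0.998, limma). Whether it lies within the part of the gene carried by the vector is not known here, so it checks nothing about the labels. The reporter probe sets did separate the groups. The brightest gave 7038 and 7458 on the HoxA13-labelled arrays against 1293 and 1454 on the controls. A second gave 109 and 76.3 against 3.7 and 2.6, both below background, at least 6.25-fold. The other 55 reporter probe sets did not exceed a signal of 33.2. Both vectors carry the reporter, and the sources do not say which of these probe sets match it. The separation therefore does not measure the HoxA13 transcript, and its cause was not tested.

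**Figure D1:**
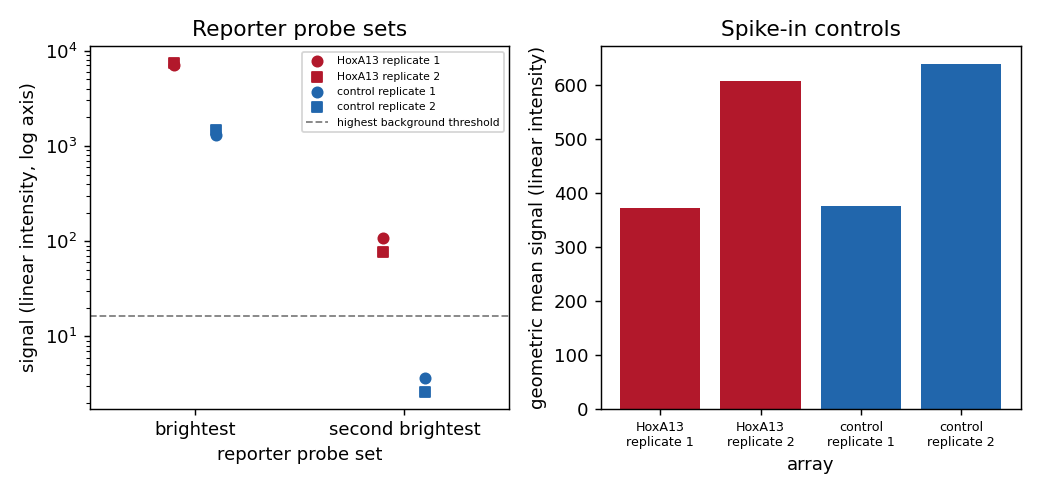
Left, signals (linear intensity, log axis) of the 2 reporter probe sets that were brighter on both HoxA13-labelled arrays, with 1 point per array and the highest background threshold dashed. Right, geometric mean signal (linear intensity) of the 27 spike-in controls per array, which was 372 and 376 on the replicate 1 arrays and 608 and 639 on the replicate 2 arrays of the HoxA13 and control groups.

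The largest difference was in CYP24A1, the enzyme that inactivates vitamin D. Its signal was 1.68 and 1.14 on the HoxA13-labelled arrays and 609 and 661 on the controls, at least 44.1-fold lower (adjusted p = 0.000169, offset fit). The vascular growth factor ANGPT2 fell at least 11.8-fold, from 141 and 205 in the controls to 0.7 and 8.91. HHEX, a homeobox gene of endoderm and early endothelium, fell from 336 and 419 to 44.2 and 9.39, of which only the first was above background. The galectin LGALS3 fell at least 6.92-fold and the synaptic vesicle gene SYP at least 5.32-fold. The probe set of the Wnt receptor gene FZD6 that passed fell at least 6.54-fold. HSPA2, a heat shock protein gene, fell 6.82-fold and DPYS, an enzyme of pyrimidine breakdown, 6.79-fold. A second and brighter FZD6 probe set differed less, with 140 and 115 against 189 and 148. The larger fold therefore may not stand for the gene.

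Fewer transcripts rose. CYP26A1, which degrades retinoic acid, rose 5.83-fold, from 103 ± 13.0 in the controls to 625 ± 258 (mean ± SD, n = 2 each, limma adjusted p = 0.0481, offset fit). RASGRP3, an activator of Ras, rose 2.92-fold to 2069 ± 189 from 707 ± 17.1, and its second probe set was also higher in both batches. The tight junction gene CLDN1 rose 2.36-fold to 5335 ± 293 from 2282 ± 436. With 2 lower probe sets that have no gene name, these make the 3 probe sets higher and 10 lower that passed the offset fit. All 13 differed in the same direction in both batches, which passing with 2 arrays per group nearly ensures.

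**Figure D2:**
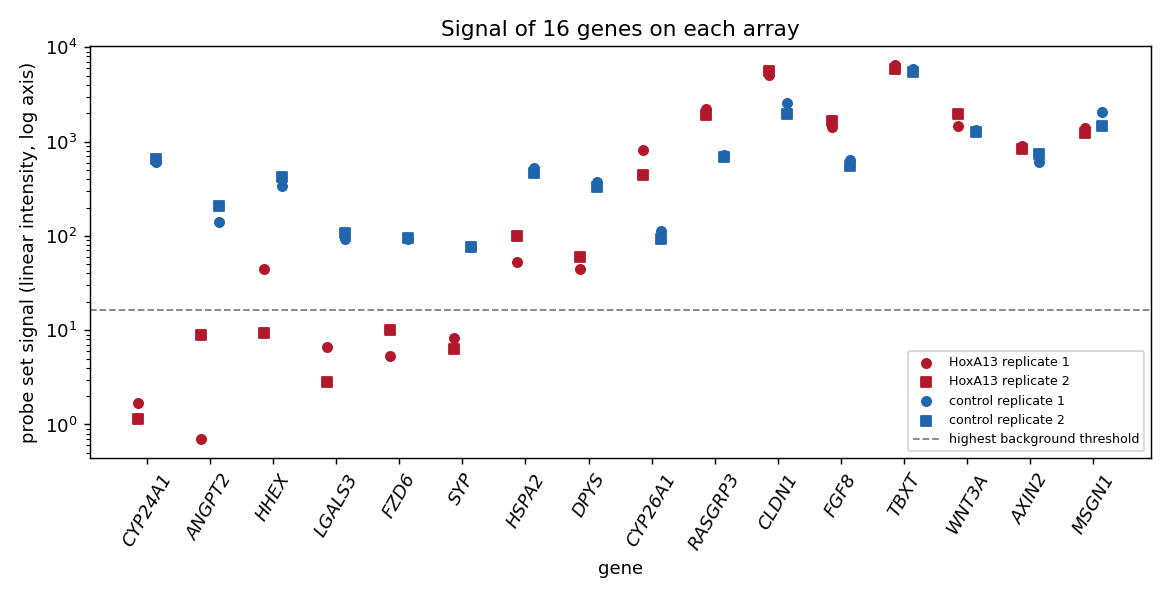
Signal (linear intensity, log axis) of 16 genes on each array, HoxA13 in red and control in blue, replicate 1 as circles and replicate 2 as squares, with the highest background threshold, 16.5, dashed. CYP24A1 was at 1.68 and 1.14 against 609 and 661, whereas TBXT was at 6483 and 5820 against 5873 and 5508. FZD6 is shown at the probe set that passed the offset fit, not at its brighter one.

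In the planned fit 0 probe sets were higher and 0 lower at an adjusted p of 0.05 in limma, with 2228 of 37695 at an unadjusted p under 0.05 against 1885 expected by chance. The smallest adjusted p was 0.62. In the offset fit 813 of 15818 had an unadjusted p under 0.05 against 791 expected by chance, almost no excess. The fit with the batch as a block gave 1593 against 791. With the batch as a block the offset fit passed 53 probe sets higher and 107 lower, among them all 13 of the fit without it. The block treats arrays of equal replicate number as a batch, which the labels do not state. Leaving out 1 array at a time changed the counts of the offset fit. It passed 0 higher without HoxA13 replicate 1 and 1 higher without HoxA13 replicate 2, 5 lower without the latter, and 23 higher and 58 lower without control replicate 1. CYP24A1, ANGPT2 and HHEX passed in each of these 4 fits. CYP26A1, LGALS3 and HSPA2 passed in 3, and RASGRP3, CLDN1, DPYS, FZD6 and SYP in 2. CYP26A1 was lost without HoxA13 replicate 1 (adjusted p = 0.212), and RASGRP3 without either HoxA13 array (adjusted p = 0.195 and 0.149).

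**Figure D3:**
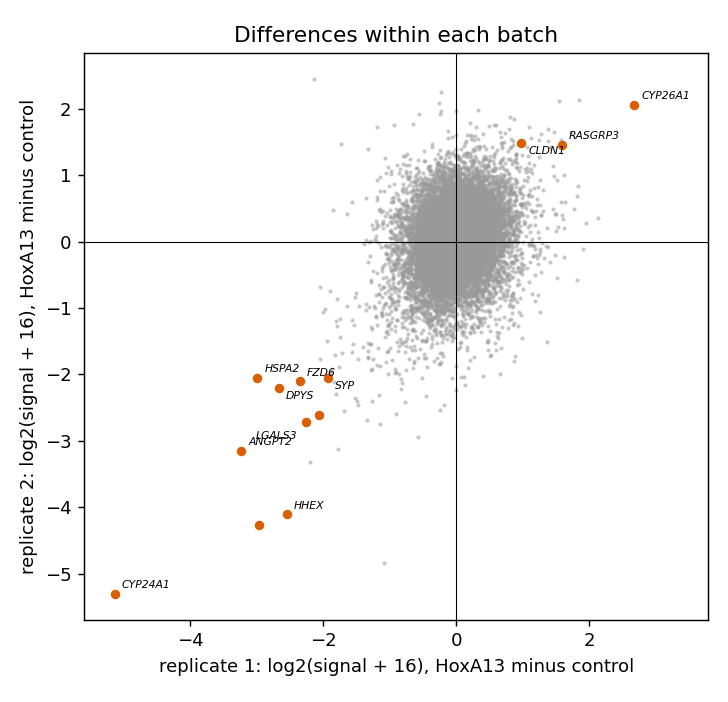
Difference in log2(signal + 16), HoxA13 minus control, between the replicate 1 arrays (horizontal) and between the replicate 2 arrays (vertical) for 15818 probe sets above background. Orange points are the 13 probe sets that passed the offset fit, and the unlabelled ones have no gene name. CYP24A1 lies at -5.14 and -5.30 and CYP26A1 at 2.68 and 2.06.

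Across the 15818 probe sets above background the differences in the 2 batches correlated weakly (Pearson 0.25, across probe sets, which are not independent). Of these probe sets, 26 were over 2-fold higher in both batches on the log2(intensity + 16) scale, 79 over 2-fold lower in both, and 9 over 2-fold in opposite directions. With the arrays paired across batches instead, the numbers were 22, 77 and 93.

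Genes of the streak and tail bud progenitors were mostly higher in the HoxA13-labelled arrays. Of 17 measured, 14 were above background, 9 of them were higher in both batches and 3 lower in both. FGF8, the main growth factor of the streak, was 1411 and 1637 against 637 and 545, 2.58-fold higher. It missed the offset fit (adjusted p = 0.0907) and rose with the block (adjusted p = 0.00041). FGF3, EVX1 and SP8 also rose with the block only, by 2.24-fold, 3.79-fold and 1.92-fold. With CYP26A1 these are 5 genes of the list that passed with the block, and 5 that passed the offset fit adjusted over the list alone. NODAL, with 3.77 and 4.01 against 1.78 and 1.73, was below background in all arrays. The core genes TBXT, WNT3A, CDX2 and CDX4 did not pass in any of these fits. TBXT, the T-box gene of the streak, was 6151 ± 468 against 5691 ± 258, WNT3A 1698 ± 357 against 1292 ± 31.7 (with -0.10 on the log2 scale at its other probe set), CDX2 515 ± 59.3 against 386 ± 7.59, and CDX4 2992 ± 295 against 2193 ± 375 (mean ± SD, n = 2). As a list the streak genes were not shifted in the planned test (camera adjusted p = 0.0704) and were shifted up in the offset fit (adjusted p = 0.000564, and 5.68e-08 with the block). With an estimated correlation the adjusted p was 0.896 in the planned fit and 0.535 in the offset fit.

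The FGF pathway list gave FGF8 and FGF3 as its 2 members that passed with the block, out of 24 measured. Their receptor FGFR1 was 150 and 142 against 79.6 and 80.4, and the target ETV1 377 and 217 against 172 and 138, and neither passed. In the other direction, a probe set of the receptor gene FGFR2 fell with the block (limma adjusted p = 0.0174). It was 29.5 and 32.9 against 118 and 95.1 and is not among the probe sets that stand for the list. The list was not shifted in the planned test (adjusted p = 0.47) or the offset fit (adjusted p = 0.105) and was shifted up with the block (adjusted p = 0.0184). With an estimated correlation the adjusted p was 0.896 in the planned fit and 0.551 in the offset fit. Retinoic acid genes went both ways. CYP26C1, a further degrading enzyme, was 55.9 and 48.2 against 17.7 and 12.2. ALDH1A2, the synthesising enzyme, was 12.8 and 4.39 against 34.6 and 31.7, below background in both HoxA13-labelled arrays and at least 2.30-fold lower. Neither passed over all genes (adjusted p = 0.411 and 0.538, offset fit). Adjusted over the 10 genes of the list above background, 2 passed as higher and 1 as lower in the offset fit. The receptor RXRG was below background on all 4 arrays. The list's adjusted p was 0.572.

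Wnt target genes showed no call in the planned or the offset fit. AXIN2, a feedback target, was 858 ± 42.5 against 677 ± 99.1, and LEF1 was near background, with 23.6 and 7.25 against 24.4 and 20.2. The members with the smallest p were SP8, CDX1 at 17.7 and 15.3 against 31.4 and 27.8, the receptor gene LGR4 at 162 and 148 against 236 and 251, and MYC at 106 and 62.3 against 70.4 and 22.5. Only SP8, also a streak gene, passed with the block. Of 13 members above background 6 were higher and 4 lower in both batches. The list had a median log2 difference of 0.11 and was not shifted (adjusted p = 0.836, and 0.204 in the offset fit). The blocked fit gave an adjusted p of 0.0481, upward, and an estimated correlation gave 0.896 in the planned fit and 0.662 in the offset fit. Among Wnt ligands, receptors and modulators, DACT2, a Wnt and Nodal antagonist, fell with the block. Its signals were 511 and 321 against 799 and 1181.

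Genes of the presomitic mesoderm and the segmentation clock gave 0 calls in any of these fits among 18 measured. MSGN1, which specifies the presomitic mesoderm, was 1321 ± 110 against 1760 ± 396 and lower in both batches. The clock gene LFNG was 1602 and 2135 against 972 and 1611. The Notch ligand gene DLL1 followed the batch, with 1888 and 934 against 2023 and 492, and its second probe set differed in the opposite direction. TBX6 and PCDH8 were below background on all arrays. JAG1, another Notch ligand gene, was at least 1.89-fold lower, HES5 was 115 and 125 against 99.4 and 49.6, and HEY1 126 ± 38.3 against 192 ± 63.5 (mean ± SD). SNAI2 was 541 ± 14.2 against 412 ± 40.0. The list's median log2 difference was -0.09, its mean 0.07, and it was not shifted (adjusted p = 0.836). Of the other posterior Hox genes, 9 were measured and 1 was above background. HOXD11, HOXD10, HOXC13 and HOXD12, those with the smallest p, were below 14.5 on every array. The list was not shifted (adjusted p = 0.384).

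Markers of other mesoderm were mostly dim. In the planned fit 9 of 14 lateral and intermediate mesoderm genes had lower values in the HoxA13-labelled arrays, as had 8 of 17 somite genes and 10 of 20 blood and endothelial genes. PRRX1, a homeobox gene of lateral mesoderm, was 16.6 and 29.9 against 109 and 113, 4.99-fold lower, and fell with the block (adjusted p = 0.00315). GATA6, PAX2 and GATA5 were below background on the HoxA13-labelled arrays and at most 24.5 on the controls. The lateral and intermediate mesoderm list was not shifted in the planned test (adjusted p = 0.0704, 0.0272 with the filter at the median, downward, and 0.896 with an estimated correlation), and only 2 of its 14 measured genes were above background, of which 1 passed lower adjusted over the list alone in the offset fit. Among somite genes, MEOX1 was 13.6 and 23.1 against 45.5 and 67.3 and PAX9 48.7 and 67.3 against 23.9 and 14.7. TBX18 was below background. None passed over all genes. Only 3 of the 17 measured genes were above background. Adjusted over these 3 alone, 1 passed higher and 2 lower in the offset fit. Each was above background in both arrays of its brighter group and in at most 1 of the other. The filter therefore favoured genes that differ, and these calls are no support for a change. The list was not shifted (camera adjusted p = 0.758). Of blood and endothelial genes, the VEGF receptor gene FLT1 was 33.6 and 0.99 against 212 and 153 and fell with the block (adjusted p = 0.000121). PECAM1, FLI1 and HBA1 were at or below 15.8 on every array. Of 20 measured genes 7 were above background, and adjusted over these alone 1 passed lower in the offset fit. The list was not shifted in the planned test (camera adjusted p = 0.836) or the offset fit (adjusted p = 0.0572). It was shifted down with the block (adjusted p = 0.00649). Of its 7 genes above background, 1 was higher in both batches, 2 lower in both and 4 opposite. FLT1 was at -2.76 in the offset fit, and the 6 others had a median log2 difference of -0.0493. An estimated correlation gave an adjusted p of 0.896 in the planned fit and 0.535 in the offset fit.

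SNAI1, a driver of the epithelial to mesenchymal transition, fell 3.37-fold with the block (adjusted p = 0.00288), with 54.9 and 83.9 against 191 and 275. The basement membrane genes NID1, COL4A1 and COL4A2 were lower in both batches and did not pass. NID1 was 112 ± 30.4 against 233 ± 22.3, COL4A1 68.6 ± 4.62 against 144 ± 42.3 and COL4A2 was 155 and 178 against 258 and 376. CDH2, the N-cadherin gene, rose with the block from 1439 and 1052 to 2373 and 2115. The transition and matrix list was not shifted (adjusted p = 0.396). Of its 24 measured genes 21 were above background, and adjusted over these alone 1 passed higher and 1 lower in the offset fit. Of the surface ectoderm genes EPCAM fell with the block, from 2603 and 1687 to 1576 and 1029, while DLX6, GRHL3 and WNT6 were near background. Of 13 measured, 6 were above background, of which 0 were higher in both batches, 2 lower in both and 4 opposite. This list was not shifted in the planned test (adjusted p = 0.384) and was shifted down in the offset fit (adjusted p = 0.0486, 0.00649 with the block, and 0.535 with an estimated correlation). Without HoxA13 replicate 2 or control replicate 2 the offset value was 0.49 or 0.143.

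Neural plate genes had an adjusted p of 0.0704 in the planned camera test, upward, 0.0146 with fry, and 0.896 with an estimated correlation. In the offset fit it was 0.0572, with the block 0.0227, and with an estimated correlation 0.535. Of 15 measured, 9 were above background, 5 of these were higher in both batches and 0 lower in both. CDH2, which is on this list too, was the only gene that passed with the block. PAX6 was 30.1 and 19.9 against 8.69 and 10.3, at least 1.68-fold higher. NEUROG1 and NEUROG2 were below background throughout. SOX2 was 16.5 and 41.5 against 7.94 and 28.3. Neural crest genes had 0 calls among 14 measured. Of these, 6 were above background, of which 4 were higher in both batches, 0 lower in both and 2 opposite. ZEB2 was 167 and 139 against 120 and 72.1, MSX1 724 and 1006 against 647 and 503, and SOX8 and SOX9 were below background. Their list had an adjusted p of 0.0704 in the planned test and was shifted up in the offset fit (adjusted p = 0.0339, 0.0133 with the block, and 0.535 with an estimated correlation). That value was 0.0548, 0.0753 and 0.167 without HoxA13 replicate 1, HoxA13 replicate 2 and control replicate 2.

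The remaining 12 lists were not shifted in the planned test. The adjusted p was 0.836 for Wnt ligands and receptors, 0.572 for TGF-beta and BMP genes, 0.572 and 0.384 for Hox genes of paralog groups 1 to 4 and 5 to 9, 0.47 for the node and notochord and 0.836 for endoderm. It was 0.384 for the cell cycle, 0.967 for p53 and apoptosis, 0.572 for heat shock and stress, 0.705 for interferon genes, 0.836 for glycolysis and 0.664 for ribosomal proteins. With the block in the offset fit the Hox genes of groups 5 to 9 (camera adjusted p = 0.0267) and the cell cycle genes (0.0481) were shifted up. The stress genes were shifted down (0.0133), and the others were not shifted. Of 30 cell cycle genes above background, 9 were higher in both batches, 0 lower in both and 21 opposite. For the 9 Hox genes above background the numbers were 5, 0 and 4, and for 16 stress genes 3, 8 and 5. The stress genes had a median log2 difference of -0.0722 in the offset fit, and only HSPA2 among them passed. With an estimated correlation the adjusted p of these 3 lists was 0.896 in the planned fit, and 0.535, 0.712 and 0.662 in the offset fit. Adjusted over each list alone, 0 genes passed the planned fit in any of the 25 lists. The median log2 difference was 0.16 over 30 cell cycle genes, 0.03 over 18 glycolysis genes and -0.02 over 58 ribosomal protein genes.

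The genes that the fixed rule took by smallest p did not pass (adjusted p = 0.62 for all). On the higher side they were EVL, RNF216, EEFSEC, PLA2G10L, SYNE1, SOX17, SERPINE3, SLC17A8, GJA5, UNKL, SRBD1 and PCDH18. On the lower side CYP24A1 was followed by DHX57, CPNE7, SPAG9, ADH1C, LYSMD4, ZNF385C, SPECC1, CHRDL1, CCDC34, JAKMIP1 and ESYT3. Of the 24 probe sets that the rule picked for them, 20 were below background on all 4 arrays, and that of CYP24A1 was the only one above it in both arrays of a group. Other probe sets of EVL, RNF216, EEFSEC, UNKL, DHX57, CPNE7, SPAG9, LYSMD4 and CCDC34 were above background on all 4 arrays. The brightest of EVL was 742 and 716 against 773 and 805, so the value of the rule's probe set does not stand for the gene.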

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

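All tests in this part were chosen after the results were seen, except the count over other splits of the arrays.

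A signal outside the chicken transcripts differed between the groups. The brightest reporter probe set was higher on the HoxA13-labelled arrays by 2.40 on the log2 scale, in data that enter no comparison of genes. Another was higher by a fitted 4.89, but both its control signals were below background, so only a difference of at least 6.25-fold was measured. A scaling difference would move the chicken probe sets as well, and their median log2 difference above background was 0.043. Scaling to the chicken signal could itself hold that median steady, but the spike-ins would then differ between the groups. Their median log2 difference, HoxA13 minus control, was 0.00313 in replicate 1 and -0.0506 in replicate 2. Together these values argue against scaling. A wrong label, a difference between the vectors and a difference in the share of electroporated cells stay open and untested.

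The lower probe sets of the offset fit form the second pattern. Degraded RNA as their whole cause would need a 3' to 5' ratio that separates the groups. In 3 of 3 control transcripts the ratio of both HoxA13-labelled arrays lay between those of the controls (mean log2 ratio 4.40 and 4.93 against 3.96 and 5.30), which argues against degradation as this ratio measures it. Fewer blood and endothelial cells in the HoxA13-labelled pools may account for ANGPT2, and for FLT1, which passed only with the block. The median log2 difference of the 6 other such markers above background was -0.0493 and the lower quartile -0.521, which met the limit first written against that cause. Only 1 of them, SOX18, had both control signals at least 2-fold above background and so could show a fall, a condition added later, and the cause stays open. SOX18 was 33.9 and 23.3 against 28.0 and 33.6, and FLT4 26.9 and 73.2 against 36.2 and 32.3.

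For the 13 probe sets that passed the offset fit, the 4 arrays allow 3 splits into pairs, too few for a share under 0.05. As many passed in 1 of the 3, the real one, and the highest of the other splits gave 0. The offset fit was picked on the real split, which favours that split in this count. At an unadjusted p under 0.05 in the offset fit, the split by replicate number gave 1936 probe sets. The real split gave 813 and the remaining one 213, so by this count the replicate number separated the arrays more than the group did. Overexpression of HoxA13, the difference the design names, remains among the open explanations.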

How the results depend on the processing

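The offset fit, the filter on background and log2(intensity + 16) were added after seeing the data, and the other alternatives were set beforehand. The planned counts of 0 higher and 0 lower stayed at 0 in most alternatives, including the replicate block and each array left out. The count lower became 1 with the filter at the median, with the trend and robust prior and with the filter on background (CYP24A1), and 1 with the floor (SYP). The offset fit gave 3 higher and 10 lower, and with the replicate block, that is with the replicate numbers treated as pairs, 53 and 107. Leaving out 1 array gave 0 to 23 higher and 5 to 58 lower in the offset fit and 0 of each in the planned fit. Lists shifted rose from 0 to 2 with the filter at the median, and to 1 with the trend and robust prior or fry, 3 in the offset fit and 10 with its block. The offset fit gave 4 to 5 lists with an array left out, and 0 with an estimated correlation or with fry. The streak list and the lateral and intermediate mesoderm list passed with the filter at the median (adjusted p = 0.0272 each). The streak list also passed with the trend and robust prior (0.00356), the offset fit (0.000564) and its block (5.68e-08), and the Wnt target list with that block (0.0481). Directions of some results that had not passed were reversed. The adjusted p was 0.953 for the clock list and 0.975 for the transition and matrix list with the mean of all probe sets, and 0.653 for the posterior Hox list with the floor. With each array left out in turn the adjusted p lay between 0.81 and 0.916 for the Wnt target list, 0.803 and 0.947 for the clock list, 0.403 and 0.944 for somite genes and 0.468 and 0.81 for blood and endothelium. The direction turned at 0.86, at 0.935 and 0.947, at 0.729 and 0.944, and at 0.537 in these lists. Single log2 differences ranged from -1.62 to 0.0864 for LEF1, -1.33 to 1.65 for TBX6, -0.61 to 1.43 for DLL1, -0.11 to 1.72 for SOX2, -0.93 to 3.53 for DAZL, -0.0522 to 0.18 for TDRD7, -0.35 to 1.10 for FLT4 and -0.39 to 0.14 for SOX18. TBX6 was -0.0425 with log2(intensity + 16). The cause of these reversals was not tested. The other named genes kept their direction. With an array left out, the lone array of a group is assumed to vary like the other group. The floor gave no value for genes below it on all arrays, and lists with fewer than 5 genes above background were not tested in the offset fit. Signal over background limits dim genes, since 15818 of 37695 probe sets were above it on at least 2 arrays.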

Other observations

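Beyond the lists, the blocked offset fit passed single genes that were chosen for naming after their values were seen, and they were not tested as a group. PTN, a heparin-binding growth factor, rose from 123 and 162 in the controls to 347 and 490 and was also higher at its other probe sets. The matrix proteoglycan gene VCAN rose 2.52-fold, its partner HAPLN1 from 380 and 276 to 1207 and 568, and the guidance gene SEMA3D from 141 and 110 to 366 and 370. FABP7 and NES, genes of neural progenitors, rose as well, FABP7 from 83.8 and 16.6 to 276 and 125 and NES from 148 and 267 to 328 and 595. BRINP1, a gene of the nervous system, rose from 27.2 and 28.4 to 99.1 and 103.

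Genes that fell in the same fit included CXCL12, a chemokine gene, at least 5.49-fold, and the laminin gene LAMA2 at least 5.24-fold. POSTN, a matrix gene of mesenchyme, fell from 178 and 296 to 39.4 and 47.8, and FGF13 from 862 and 878 to 354 and 246. CNTN4 fell from 277 and 242 to 55.0 and 59.7 and MTUS1 from 190 and 288 to 44.2 and 18.9. Other CNTN4 probe sets were near background. Simulated data without a batch difference gave 13.7% false calls for this fit, and the share here is not known, so single genes here are open.

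DDX4, the vasa gene of germ cells, was 3.75 and 1.77 against 42.2 and 40.1 and fell with the block (adjusted p = 0.00661, limma). DND1, another germ cell gene, was 3.99 and 3.72 against 15.6 and 28.0 and did not pass (adjusted p = 0.252). A hypothesis is that the HoxA13-labelled pools held fewer germ cells. Its test, fixed before the values were looked at, took 5 other germ cell markers above background, whose median log2 difference was 0.24 with a lower quartile of 0.06. That met the limit set in advance against the hypothesis. The limit was ill chosen, because only 2 of the 5, PIWIL1 and TDRD7, had both control signals at least 2-fold above background and so could show a fall. PIWIL1 was 187 and 154 against 130 and 137 and TDRD7 116 and 121 against 123 and 104, and somatic cells may express both. DAZL was below background on all arrays. Whether germ cells were fewer is therefore open.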
